A study of Bos taurus with 10 samples.

How the data were processed

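Poly(A) RNA from skeletal muscle of 10 Hanwoo cattle was measured on 10 Affymetrix GeneChip Bovine Genome Arrays, a 1-colour array that reads each transcript with a set of short probes, the probe set. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was purified with an oligo(dT) resin, and biotin labelling followed the array maker's protocol. The deposited values are 1 linear intensity per probe set and array, already summarised by the authors. The software that made them is not given in the sources used here. The values themselves show a common scaling, because the mean over probe sets without the lowest and highest 2% was between 500.177 and 500.203 on every array. The lowest deposited intensity was 0.0972 and the highest was 117382.

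The labels give 1 group of 10 samples and no trait values, so no group was compared with another and no trait was tested. Nothing but the sample numbers and the design text marks the samples as separate cattle. The p-values take the 10 samples as independent and hold only if they are. All 10 value columns were used. The number of arrays limits the precision of every estimate.

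Intensities were turned into log2(signal + 16). The 10 array medians on this scale spanned 0.24, above the limit of 0.2 set in advance for keeping the deposited scaling, so the values were quantile normalized, which gives every array the same distribution. A fold change on this scale understates the change of dim genes. The 112 control probe sets were left out of normalization and tests. Of the other 24016 probe sets, 13292 had 1 gene symbol in the platform annotation, 86 had several and 10638 had none listed, and the last 2 kinds were never named. Symbols were looked up in a table of the ARS-UCD2.0 assembly, which changed 0 of them, and that table was used for names only. Where a gene had several probe sets, as 2913 genes did, the brightest was used. A gene was tested if its mean was above the median of all probe sets outside the controls, a log2 level of 6.98. This left 6271 of 9155 named genes. Another 4122 unnamed probe sets passed the same filter and were tested apart from the genes.

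Gene lists were fixed before the data were examined. The 23 lists held 380 entries for fibre types, energy metabolism, fat, connective tissue, protein turnover, stress, immunity, other cell types and sex-linked genes, of which 308 were measured and 260 tested. The sex-linked list had no tested member. The list score of an animal is the mean, over tested members, of each gene's deviation from its mean over the 10 animals. For each list with 3 or more tested members, the median SD of the members was set against 10000 random lists of equal size. They were matched on deciles of mean level.

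Covariation was tested with limma version 3.58.1 in R version 4.3.3, with a list score in SD units as covariate and the Benjamini-Hochberg adjustment at 0.05. The 3 scores were the adipocyte score, the slow minus fast fibre score and the connective tissue score. A list member was fitted against the score without it, and counts of genes leave out the members of the score's own list. Correlations between scores used two-sided permutation tests with 100000 resamples, and Benjamini-Hochberg adjustment over all 55 pairs. Each r was ranked among those of 1000 random lists of the same size matched on mean level. With 9 or fewer samples, every permutation was enumerated.

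Genes were named by a rule set in advance. It takes the 15 tested genes with the highest mean, the 25 with the largest SD and, for each covariation fit, up to 12 genes per direction with the largest slopes among those past the test. If fewer than 5 genes pass, it takes the 5 with the smallest p in each direction. Members of the fixed lists add 2 to 4 genes per list, the brightest and those at the ends of SD or slope.

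The fits were tested on simulated data with 200 changed genes. Each gene was drawn independently of the others, so these shares of recovered and false calls need not hold for real genes, which vary together. For the adipocyte fit over 6260 genes, 44% of genes with a slope of 0.5 and 96% of genes with a slope of 1 were recovered, and 14 of 154 calls were false. For the fibre fit over 6253 genes these were 53% and 93%, with 6 of 152 calls false. For the connective tissue fit over 6255 genes they were 63% and 96%, with 7 of 166 calls false. The permutation test called 5% of simulated independent pairs.

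Alternatives fixed in advance were the deposited scaling, centring on the median, no filter, a filter at the 75th percentile, pseudocounts of 1 and 64, the mean of a gene's probe sets, each animal left out in turn, the GAPDH and actin 3' to 5' difference as a covariate, Spearman correlation per gene, other list scores and another variance prior. Both actin and GAPDH controls were available, the actin probe sets being annotated to ACTA1. Alternatives chosen after seeing the data left out animals 3 and 7, or 3, 5 and 7, or used the poly(A) control 3' to 5' difference or the hybridization control level as a covariate.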

Results

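Gene expression was measured in the longissimus dorsi, the long muscle of the back, of 10 Hanwoo, a Korean beef breed. The study set out to relate expression to beef traits of the same cattle. Trait values were not used here, so the data are described by the level of each gene, its spread between animals and its covariation with 3 gene scores. The animals form 1 group and are numbered 1 to 10. The median deposited intensity per array lay between 111 and 134.

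The arrays differed in the scaled signal of their bright probe sets and in the 3' minus 5' signal of added control RNAs. The hybridization controls, added at a fixed amount, spanned 1.98 on the log2 scale, a 3.94-fold range. These controls were read after the common scaling, so their level is no direct measure of array brightness. Their level rose with the mean of the 100 brightest probe sets (r = 0.903, permutation p = 0.00041, rho = 0.758, permutation p = 0.0149, n = 10), and r was 0.821 without the 2 arrays farthest from the median. Correlations between pairs of arrays ran from 0.901 to 0.959 with a median of 0.933, and no pair held identical values. Animal 5 stood apart. Its 3' minus 5' signal of the added poly(A) control RNAs was 3.06 on the log2 scale, against 1.18 to 1.52 in the other 9 animals, and its score on the first principal component, which held 30.6% of the variance, was 53.2 against -14.3 to 3.12.

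**Figure D1:**
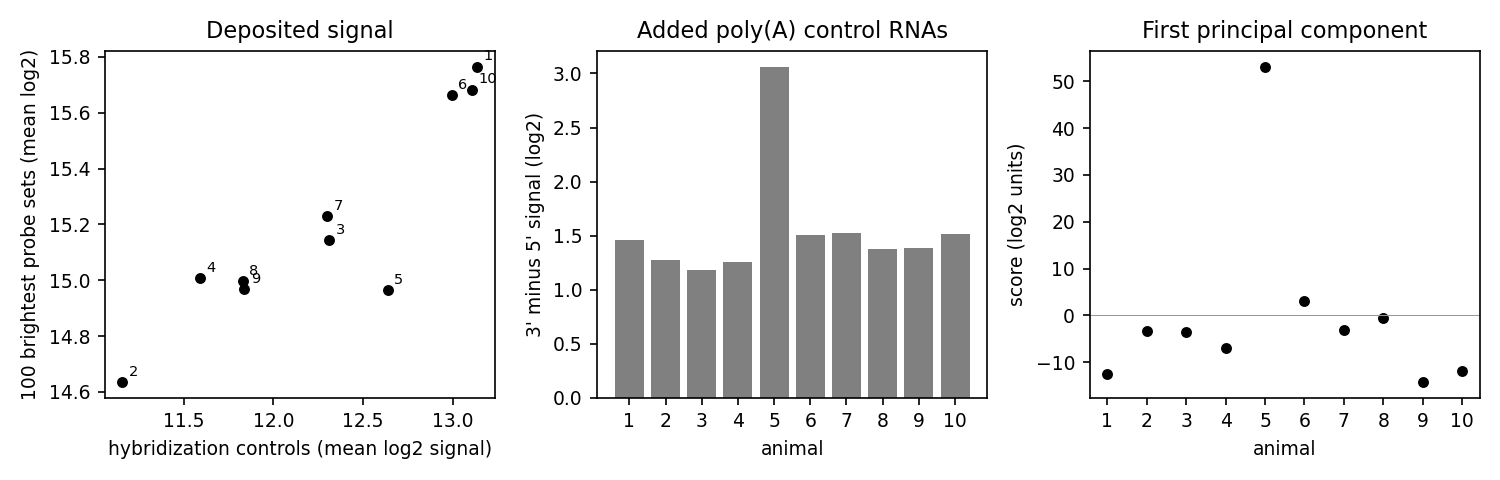
Left, mean log2 deposited signal of the 100 brightest probe sets against that of the hybridization controls, 1 numbered point per animal (r = 0.903). Middle and right, bars give the 3' minus 5' log2 signal of the poly(A) control RNAs and points the first principal component score of each animal; animal 5 is highest in both, at 3.06 and 53.2.

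Probe sets of contractile and glycolytic genes gave signals at the top of the array's range. Among the 15 genes with the highest means were the slow and cardiac troponin C gene TNNC1 at 16.05 ± 0.04 (SD, n = 10), the muscle creatine kinase CKM at 15.90 ± 0.11 and FHL1 at 15.88 ± 0.04. The fast troponin TNNI2 stood at 15.82 ± 0.07 and the slow myosin heavy chain MYH7 at 15.79 ± 0.08. GAPDH, MYL1, TNNT3, TNNC2, ENO3, ACTA1, PYGM, MYL2, LDHA and TPT1 were the other 10, with means from 15.63 to 15.76. The order among them is not read, since signals of different probe sets are not on 1 scale and TNNC1 held 16.07, the highest value that quantile normalization assigns, in 8 of 10 animals. Other probe sets of some of these genes were far dimmer, and with the mean of a gene's probe sets MYH7 stood at 11.68, CKM at 12.69, LDHA at 12.15 and TPT1 at 12.47. Of the 18 tested slow and fast fibre genes, 14 had a mean above 15. After quantile normalization the median SD was 0.15 over 9 slow fibre genes, 0.12 over 9 fast fibre genes and 0.20 over 12 glycolysis genes. These lay at the 0.03, 0 and 1.1 percentiles of random lists matched on deciles of mean level. That match is coarse at the top of the range. Random lists for the slow fibre genes (median level 15.34) and for the TCA cycle genes (13.10) both had a median SD of 0.31. The low percentiles may therefore reflect the signal limit. The small SDs also depend on the normalization, since with the deposited scaling the medians were 0.51, 0.52 and 0.46. Glycolysis genes ran from LDHA at 0.10 to PKM at 0.63. Oxidative phosphorylation genes, 47 in all, had a median SD of 0.26 (5.95 percentile), which was 0.15 without animal 5, from COX5B at 0.08 to COX6A2 at 0.74.

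Fat, connective tissue, myogenic and early response genes varied most between the animals. Over 6271 tested genes the median SD was 0.36, with 0.18 at the 5th and 0.75 at the 95th percentile, and 1384 genes (22.1%) had an SD over 0.5. Without animal 5 this count was 908. Of 20 lists, 8 had a median SD above the 95th percentile of random lists. The connective tissue list had a median SD of 0.77 and the adipocyte list 0.75, both at the 100 percentile; among genes above the 75th percentile of mean level the adipocyte median was 0.47. The myogenic list, with 6 tested members, had 0.86 (0.59 without animal 6) and the immediate early list 0.69, both also at the 100 percentile. The glucocorticoid and circadian list (0.63, 99.9 percentile), the leukocyte list (0.61, 98.2 percentile), the lipogenesis list (0.46, 97.9 percentile) and the MHC list (0.50, 96.4 percentile) followed. The heat shock list (0.37, 86.8 percentile), the calpain and cathepsin list (0.41, 91.3 percentile) and the smooth muscle list (0.43, 92.8 percentile) lay below that limit. So did fatty acid oxidation (0.36, 73.7 percentile), the TCA cycle (0.30, 43.6 percentile), proteasome and atrophy (0.33, 65.6 percentile; 0.22 without animal 5), endothelium (0.37, 50.6 percentile) and interferon (0.55, 79.4 percentile). Red cell and nerve markers had too few tested members, 1 and 2, to be set against random lists. The hemoglobin gene HBA stood at 6.99 ± 0.36 and the glial gene S100B at 10.93 ± 0.39.

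**Figure D2:**
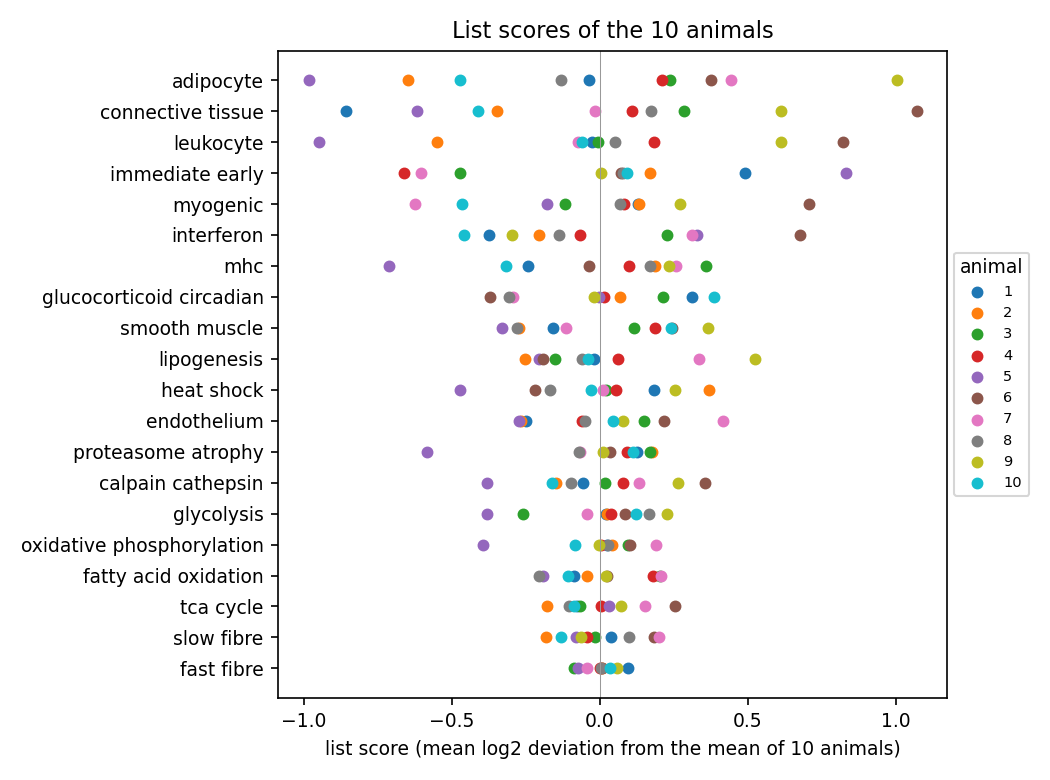
List scores of the 10 animals, in mean log2 deviation from the mean of the animals, with 1 coloured point per animal and lists ordered by the SD of the score. Adipocyte scores run from -0.98 in animal 5 to their highest value in animal 9, and fast fibre scores, of genes near the top of the signal range, from -0.09 to 0.09.

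Among single genes, 3 of liver-made plasma proteins had the largest SDs. The fibrinogen chain FGG had an SD of 2.86, transferrin (TF) 2.60 and haptoglobin (HP) 2.44. Another 2 genes of such proteins, VTN and the complement gene C3, were further down the 25 most variable genes with 1.57 and 1.37. All 5 were highest in animals 3 and 7. Without animals 3, 5 and 7 the SD of FGG was 1.87 and that of C3 0.60. FGG stood at 12.28 and 12.49 in these animals, at 9.71 in animal 10 and between 4.16 and 8.64 in the other 7. The muscle genes MYBPH, a myosin binding protein, and ACTC1, the cardiac actin, came next after HP, with SDs of 2.21 and 2.01. The immediate early genes ATF3, EGR1 and FOS had SDs of 1.65, 1.65 and 1.47; that of EGR1 was 1.04 without animal 5 and 0.86 as the mean of its probe sets. FABP4, the adipocyte fatty acid binding protein, had 1.62 and the adipokine ADIPOQ 1.41. The embryonic myosin MYH3 had 1.38, with 11.32 in animal 6 and at most 8.09 in any other; without animal 6 its SD was 0.51. LOC515676, LOC100174924, S100A2, PCBD1, RNASE6, GDF7, CSN2, ASIP, LOC513055, KERA, ASCC1 and GPA33 completed the 25 most variable genes, with SDs from 1.28 to 1.52. The LOC100174924 value rested on animal 3, without which its SD was 0.66. The CSN2 probe set, at a mean of 12.79, had r = 0.06 and -0.15 with the other 2 probe sets annotated to CSN2, at 5.33 and 4.95, and its SD was 0.51 as the mean of all 3. The PCBD1 probe set carries the same cluster number as that of the liver gene APOA2, so the identity of both CSN2 and PCBD1 signals is uncertain. The SD of GDF7 was 0.91 as the mean of its probe sets.

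Probe sets of the same gene shared part of this spread. Over 1315 genes with at least 2 tested probe sets, the median r between the 2 brightest was 0.343, against 0.011 for random pairs of probe sets of different genes matched on mean. FABP4 probe sets had r = 0.914, FOS 0.913, GDF7 0.955 and MYBPH 0.866, while EGR1 probe sets had r = 0.099. Another GDF7 probe set, dim at 5.79, had r = 0.346 with the brightest. These values are across genes, which are not independent replicates.

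**Figure D3:**
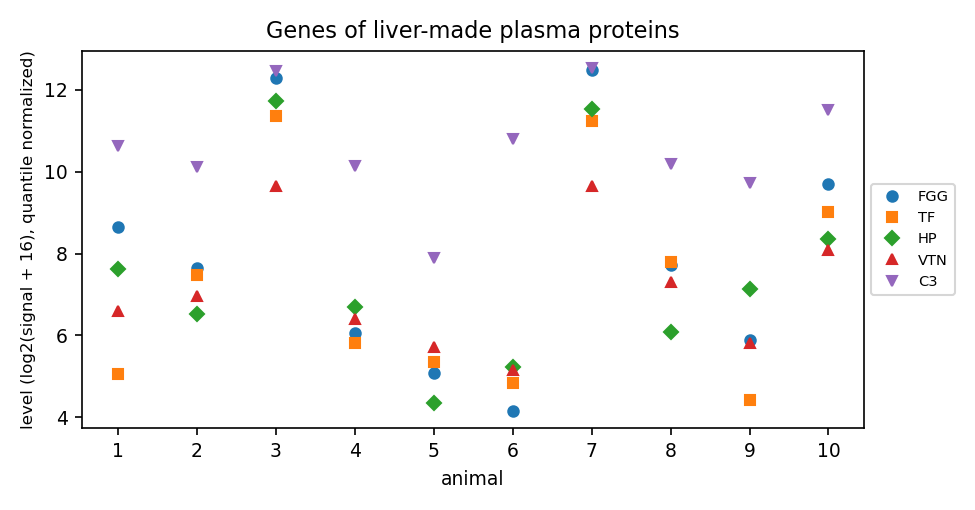
Log2 level of FGG, TF, HP, VTN and C3 in each of the 10 animals, 1 symbol per gene. Animals 3 and 7 are highest for all 5 genes, with FGG at 12.28 and 12.49, and animal 10 is next at 9.71.

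The adipocyte score asked which genes varied with fat cell markers across the animals. RNASE6, G0S2, C1QA, ANXA2, S100A11 and SPARC were among the genes that rose with it. In limma, 15 of 6260 genes outside the list rose and 0 fell at an adjusted p below 0.05, and 809 had an unadjusted p below 0.05. RNASE6, a ribonuclease of immune cells, had the steepest slope at 1.28 log2 per SD of the score (SE 0.19, adjusted p = 0.0161). G0S2, an inhibitor of triglyceride breakdown, followed at 1.07 (SE 0.19, adjusted p = 0.0398). The complement gene C1QA rose by 0.85 (SE 0.09, adjusted p = 0.00307), and its partner C1QB by 0.54 (adjusted p = 0.029). The calcium and membrane binding genes ANXA2 (0.82), S100A11 (0.80) and ANXA1 (0.70) rose with adjusted p = 0.0246, 0.00382 and 0.0306 in limma. The chaperone CLU rose by 0.74 (adjusted p = 0.0264) and the matrix protein gene SPARC by 0.71 (adjusted p = 0.0246). LOC504773 (0.81), EPHX1 (0.61), OLFML1 (0.59) and GLIPR2 (0.57) rose with adjusted p = 0.0137, 0.0484, 0.0398 and 0.0484. Without animal 5 the slopes of ANXA2 and EPHX1 were 0.53 and 0.41. The OLFML1 slope was 0.24 as the mean of its probe sets, whose r was 0.098. Another 2 unnamed probe sets of 4122 rose.

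**Figure D4:**
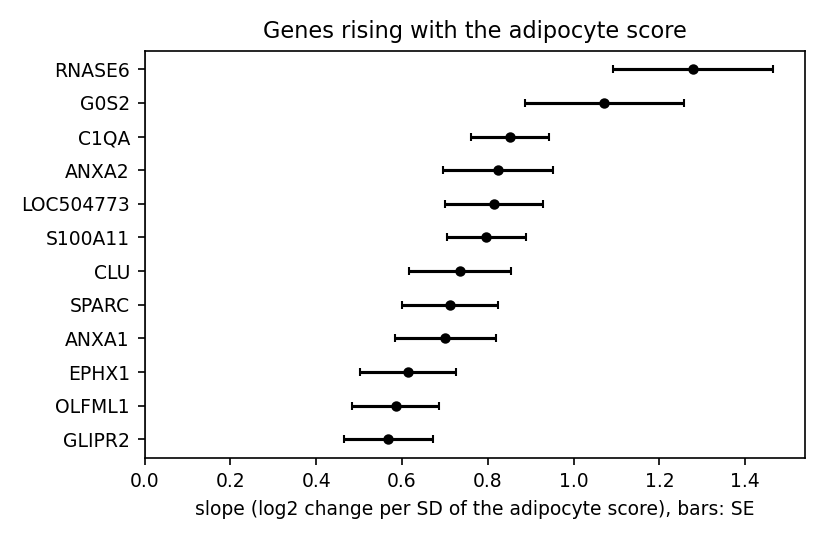
Slopes of the 12 named genes that rose with the adipocyte score, in log2 change per SD of the score over 10 animals; bars are standard errors from limma. Slopes run from 0.57 for GLIPR2 to 1.28 for RNASE6.

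Within the fixed lists, 1 of 11 adipocyte genes rose with the score made without it, and 5 did so adjusted over the list alone. It was FABP4, at 1.53 (SE 0.16, adjusted p = 0.0016). ADIPOQ (1.03, adjusted p = 0.169) and CIDEC (0.94, adjusted p = 0.09) did not pass over all genes, and GPAM had the smallest slope at 0.02. Of 9 leukocyte genes 2 rose, the C1Q genes above, and 5 adjusted over the list alone; all 9 slopes were above 0. Of 16 connective tissue genes 1 rose, SPARC, and 7 adjusted over the list alone, with all 16 slopes above 0. No calpain or cathepsin gene of 12 passed over all genes, and 4 rose adjusted over the list alone; CTSS and CTSK each had a slope of 0.53 (adjusted p = 0.19 and 0.156). Adjusted over the list alone, 2 of 20 fatty acid oxidation genes rose, ECI1 and UCP3 (0.50), and 1 of 8 smooth muscle genes, ACTA2 (0.47), and 0 of either list over all genes. PER2, the only circadian list gene of 7 that fell adjusted over the list alone, had -0.49 (adjusted p = 0.122 over all genes). In the lists of lipogenesis, slow and fast fibre, glycolysis, TCA cycle, oxidative phosphorylation, proteasome and atrophy, heat shock, immediate early, endothelium, myogenic, interferon, MHC, red cell and nerve genes, 0 members passed either way. FASN had 0.32 and EGR1 -1.11, neither past the test (adjusted p = 0.352 and 0.251).

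The adipocyte score had r = -0.562 with the 3' minus 5' signal of the poly(A) controls (permutation p = 0.124, adjusted p = 0.745 over 6 pairs of a score and an array measure, rho = -0.127, permutation p = 0.733), with r = 0.083 without animal 5 and 0.176 without the 2 farthest animals. Its r with the hybridization control level was -0.081 (permutation p = 0.822, adjusted p = 0.917, rho = -0.018, permutation p = 0.973), with r = -0.429 without the 2 farthest. A Spearman correlation per gene called 17 genes, 12 that rose and 5 that fell, of which 4 were among the 15. C1QA and S100A11 passed with each of the 10 animals left out in turn. The count of 15 was 7 without animal 2, 6 without animal 3, 6 without animal 4, 3 without animal 5 and 2 without animal 9. Without animals 3 and 7 it was 2, without animals 3, 5 and 7 it was 0, and with the poly(A) control difference as a covariate it was 3.

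The slow minus fast fibre score, a contrast of both fibre lists, was used to test fibre type covariation. It had an SD of 0.14 and no gene passed. Its own members did not follow it: against the score made without each, 6 of 9 slow fibre slopes were above 0 (median 0.01, MYL3 at -0.09) and 4 of 9 fast fibre slopes were (median -0.01), and 0 of either list passed, also adjusted over the list alone. The score is therefore no established measure of fibre makeup in these data. In limma 0 of 6253 genes were past the threshold, 392 had an unadjusted p below 0.05, and a Spearman correlation per gene also called 0, with 529 at an unadjusted p below 0.05. The 5 smallest p with positive slopes belonged to PTGER4, PTPN3, COL27A1, CROT and SH3YL1, and those with negative slopes to ZFP36, SLC4A2, ABL1, ETS2 and FGFR4, all with adjusted p = 0.574. In the lists, RSAD2, an interferon response gene, rose adjusted over the list alone (0.46) and ZFP36, which binds unstable transcripts, fell (-0.64); both have adjusted p = 0.574 over all genes, and 0 members of the other lists passed adjusted over the list alone. The fibre score had r = 0.045 with the poly(A) control difference and 0.227 with the hybridization control level (permutation p = 0.917 and 0.522, adjusted p = 0.917 for both, rho = 0.212 and 0.103, permutation p = 0.56 and 0.786), with r = 0.479 and 0.047 without the 2 farthest animals.

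MGP, CD68, MEG3, TGFBI and IGFBP4 rose with the connective tissue score. In limma they were the 5 genes that rose of 6255, 0 fell, and 526 were at an unadjusted p below 0.05. MGP, an inhibitor of calcification in matrix, rose by 0.94 per SD of the score (SE 0.13, limma adjusted p = 0.0287). TGFBI, a matrix protein induced by TGF-beta, rose by 0.62 (adjusted p = 0.0287) and IGFBP4, a binding protein of insulin-like growth factors, by 0.49 (adjusted p = 0.0444). The macrophage marker CD68 rose by 0.70 and the noncoding RNA gene MEG3 by 0.64, both with adjusted p = 0.0455; the MEG3 slope was 0.41 as the mean of its probe sets. Within the score's own list, 1 of 16 genes rose with the score made without it, FN1 at 0.71 (adjusted p = 0.0312), and 16 of 16 did so adjusted over the list alone. FMOD had the largest slope at 0.88 and COL6A1 the smallest at 0.20. Of 9 leukocyte genes 1 rose, CD68, and 5 adjusted over the list alone. Adjusted over the list alone, 3 of 11 adipocyte genes, 4 of 12 calpain and cathepsin genes, 1 of 8 smooth muscle genes (RGS5), 1 of 2 nerve genes (S100B), 1 of 6 myogenic genes (MYH3, whose spread rests on animal 6) and 1 of 8 MHC genes (TAP1) rose. The other lists had 0. A Spearman correlation per gene called 8 genes, 6 that rose and 2 that fell. The score had r = -0.370 with the poly(A) control difference and -0.156 with the hybridization control level (permutation p = 0.298 and 0.667, adjusted p = 0.895 and 0.917, rho = -0.394 and -0.309, permutation p = 0.264 and 0.387), with r = 0.064 and -0.128 without the 2 farthest animals. The count of 5 was 10 without animal 5, 1 without animal 10, and 0 without any of animals 2, 4, 6, 7, 8 and 9, or without both 3 and 7.

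Scores of whole lists were compared over 55 pairs, of which 15 had an unadjusted permutation p below 0.05 and 1 passed the adjustment. The calpain and cathepsin score, over both protease families, the calpain subunit gene CAPNS1 and the inhibitor genes CAST and CST3, rose with the adipocyte score (r = 0.909, permutation p = 0.00053, adjusted p = 0.0291, rho = 0.939, permutation p = 0.00022, adjusted p = 0.0121, n = 10). Without the 2 animals farthest from the median adipocyte score r was 0.837, and with each animal left out in turn it stayed between 0.858 and 0.977. The adjusted p was above the threshold of 0.05 without each of animals 2, 3, 4, 5, 7, 8 and 10, where 0 pairs passed, and when arrays were centred on their median. Without animal 1 or animal 6, 3 pairs passed. Scores tended to share direction, with r above 0 in 42 of the 55 pairs, so each r was also ranked among 1000 random lists matched on mean level. This r lay at the 99.8 percentile.

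**Figure D5:**
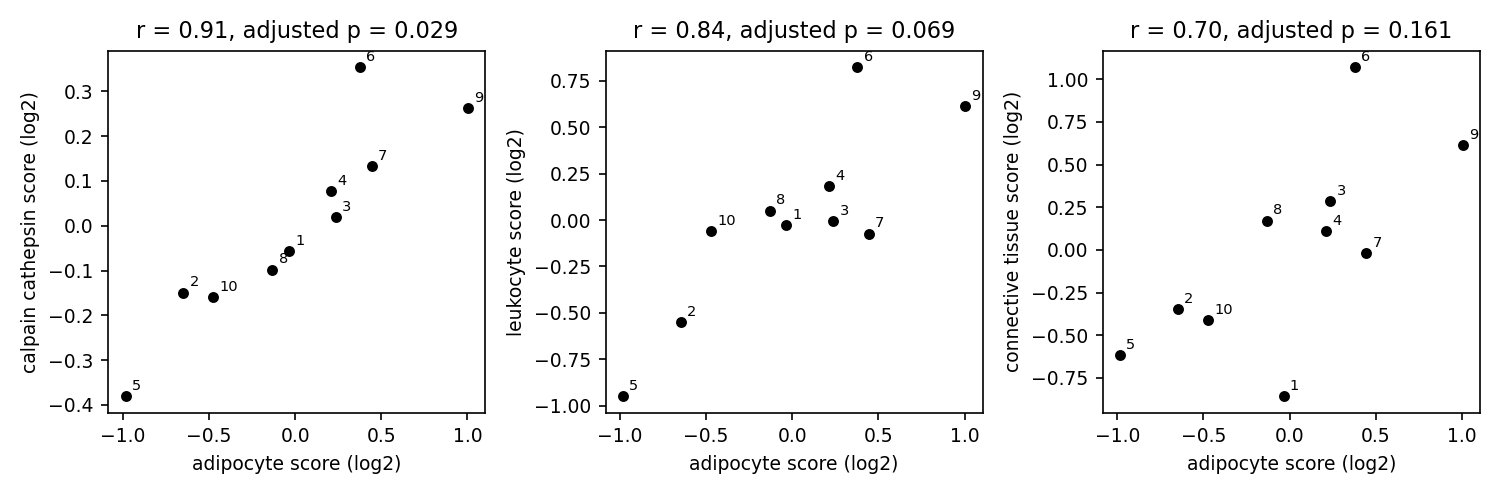
Calpain and cathepsin, leukocyte and connective tissue scores against the adipocyte score, in mean log2 deviation, 1 numbered point per animal (n = 10). r is 0.909, 0.842 and 0.697, and only the first pair passed the adjustment over 55 pairs.

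The other 14 pairs with an unadjusted p below 0.05 did not pass the adjustment, and the 7 with the largest r in size were these. The leukocyte score had r = 0.842 with the adipocyte score (permutation p = 0.00319, adjusted p = 0.0691, rho = 0.661, permutation p = 0.0432) and r = 0.795 with the connective tissue score (permutation p = 0.00629, adjusted p = 0.0865, rho = 0.794, permutation p = 0.00847). The calpain and cathepsin score had r = 0.823 with the connective tissue score (permutation p = 0.00377, adjusted p = 0.0691, rho = 0.745, permutation p = 0.0176). The interferon score had r = 0.778 with the fibre score (permutation p = 0.00904, adjusted p = 0.0994, rho = 0.77, permutation p = 0.0124). It rests on only 3 tested genes of the 17 in its list, and the fibre score is no established measure of fibre makeup. The lipogenesis score had r = 0.740 with the adipocyte score (permutation p = 0.0135, adjusted p = 0.124, rho = 0.673, permutation p = 0.0394). The glucocorticoid and circadian score had r = -0.713 with the fibre score (permutation p = 0.0224, adjusted p = 0.161, rho = -0.685, permutation p = 0.0342). Adipocyte and connective tissue scores had r = 0.697 (permutation p = 0.0253, adjusted p = 0.161, rho = 0.685, permutation p = 0.0353). Without the 2 animals farthest from the median of the first score in each pair, r was 0.657 for the adipocyte and leukocyte scores, 0.883 for the connective tissue and leukocyte scores, 0.870 for the connective tissue and protease scores, 0.619 for the interferon pair, 0.482 for the lipogenesis pair, -0.445 for the circadian pair and 0.575 for the last. Among random lists, r lay at the 98.7 percentile for the adipocyte and leukocyte scores, at 97.5 for the connective tissue and leukocyte scores, at 99.8 for the connective tissue and protease scores and at 99.3 for the interferon pair. The lipogenesis pair lay at the 93.9, the circadian pair at the 0.7 and the adipocyte and connective tissue pair at the 88.9 percentile.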

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

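The tests of labelling and of the hybridization control level for animal 5 were chosen after its values were seen. In 11 of 92 sets of 10 values, 1 animal had a gap to the next above Dixon's 95% critical value for 10 samples. The gap is taken as a share of the whole range. Chance alone gives about 1 in 20 for independent sets not picked by their values. That rate is no measure here, since some genes were picked for spread or slope and all sets share the same arrays. Animal 5 accounts for 9 of the 11. Its oxidative phosphorylation score was -0.39, with the next animal at -0.09, and its proteasome and atrophy score was -0.58, with the next at -0.07. Its levels of the bright genes TNNI2 (15.66), GAPDH (15.45), ENO3 (15.31) and TPT1 (15.36) were the lowest of the 10. So was that of the annexin gene ANXA2 (9.64, next 11.06). Its 3' minus 5' signal of the poly(A) control RNAs (3.06) and its first principal component score (53.2) were the highest. The TPT1 value rests on 1 probe set, which had r = -0.50, -0.22 and -0.04 with other bright TPT1 probe sets. With dim ones it had r = 0.33 and 0.71.

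Uneven labelling of this array is a candidate explanation for the animal 5 pattern. The gap of its poly(A) control difference was 0.819 of the range, above that critical value, and the 3' minus 5' difference was highest in animal 5 for 7 of 9 controls taken singly, among them bovine GAPDH (0.71, next 0.17) and eIF-4E (6.19, next 4.05), while animal 5 ranked 5 for actin and for the poly(A) control DapX. The scaled hybridization control level as the cause is argued against by the 3 arrays where it was higher. Their highest first component score was 3.12 against 53.2. Array brightness itself cannot be tested this way, because that level is read after the common scaling. No biological explanation was tested, since the samples form 1 group. The bovine controls among the 7, such as GAPDH and eIF-4E, read the sample's own RNA. They cannot tell labelling from the state of that RNA. Of the added poly(A) controls taken singly, LysX (4.51, next 2.51) and PheX (3.26, next 2.31) were highest in animal 5. A true difference of this animal, or of its RNA, stays open beside uneven labelling.

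LOC100174924 was 13.95 in animal 3, with the next animal at 10.69. The embryonic myosin MYH3 was 11.32 in animal 6, with the next at 8.09.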

How the results depend on the processing

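Alternatives chosen after seeing the data were those without animals 3 and 7, without animals 3, 5 and 7, and with the poly(A) or hybridization control as a covariate; the cause of each shift below was not tested, except that fewer animals, or other numbers of genes, enter some settings by construction. The adipocyte count of 15 was 7 with no filter, 8 above the 75th percentile, 2 to 18 with each animal left out, 2 without animals 3 and 7, 0 without 3, 5 and 7, 2 with the GAPDH and actin covariate, 3 with the poly(A) covariate, 9 with the hybridization covariate, 2 with the first principal component as score and 26 with the trend and robust prior. A Spearman correlation per gene gave 17, of which 12 rose and 5 fell and 4 were shared with the 15. The fibre count of 0 was 1 above the 75th percentile and 0 with each animal left out. The connective tissue count of 5 was 2 when centred, 0 with no filter, 2 above the 75th percentile, 3 with the mean of probe sets, 0 to 10 with each animal left out, 0 without 3 and 7, 0 with the GAPDH and actin covariate, 9 with the poly(A) covariate, 3 with the hybridization covariate, 8 with Spearman and 2 with the trend and robust prior. The count of 1 correlated pair was 0 when centred, 2 with no filter, 3 above the 75th percentile, 3 with the mean of probe sets, 0 to 3 with each animal left out, 0 without 3 and 7, 0 without 3, 5 and 7, 2 with the GAPDH and actin covariate, 2 with the poly(A) covariate, 4 with the hybridization covariate, 0 without the 2 farthest animals and 5 with list medians. The 1384 genes with an SD over 0.5 were 3621 with no filter, 620 above the 75th percentile, 908 with a pseudocount of 64 and 908 to 1494 with each animal left out. The 8 lists of wide spread were 4 above the 75th percentile and 7 to 11 with each animal left out. With the first principal component as fibre score, slopes changed sign for PTGER4 (-0.0295), COL27A1 (-0.0794), ZFP36 (0.0353), SLC4A2 (0.0160), ETS2 (0.0905) and FGFR4 (0.0686), none of which had passed. The median probe set r stayed between 0.182 and 0.455 over 18 settings. The named adipocyte genes kept a positive slope in all settings run, and C1QA passed in 22 of 24 and S100A11 in 23 of 25. No paired analysis was possible because the samples form 1 group. The filter worked on the mean over animals, so genes near background in single animals stayed in, such as FGG (4.16 in animal 6) and RNASE6 (4.66 in animal 5), and the liver genes were not filtered; signals near the top of the range limit the fibre genes.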

Other observations

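The gene pairs, the split of the protease list and the hybridization control test for the liver genes were chosen after the data were seen. So were the test of enzymes above the filter level in 2 animals and the leave-one-out of the leukocyte minus endothelium score. Adjustment over the few pairs tested does not cover that choice. The immediate early genes FOS and EGR1 rose and fell together across the 10 animals (r = 0.907, permutation p = 0.0007, adjusted p = 0.0035 over 5 pairs, rho = 0.721, permutation p = 0.0226), with r = 0.787 without animal 5 and 0.626 without the 2 animals farthest from the median. Animal 5 was highest for both, FOS at 14.69 (next 12.78) and EGR1 at 13.85 (next 11.02). The brightest EGR1 probe set had r = 0.099 with the gene's next one, so the EGR1 value rests on 1 probe set. The muscle genes ACTC1 and MYBPH had r = 0.717 (permutation p = 0.0203, adjusted p = 0.0301, rho = 0.806, permutation p = 0.00737) and r = 0.519 without the 2 farthest. The developmental myosins MYH3 and MYH8 had r = 0.899 (permutation p = 0.025, adjusted p = 0.0301) but rho = 0.382 (permutation p = 0.278) and r = 0.444 without the 2 farthest, so the relation rests on those animals. FOS and ATF3 had r = 0.772 (permutation p = 0.0104, adjusted p = 0.026, rho = 0.709, permutation p = 0.026), with r = 0.537 without the 2 farthest. EGR1 and ATF3 had r = 0.700 (permutation p = 0.0301, adjusted p = 0.0301, rho = 0.6, permutation p = 0.0736), with r = 0.287 without the 2 farthest.

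The 12 tested genes of the protease list were split after the data were seen, giving 6 correlations. The parts were 6 cathepsins and 5 calpain system genes, the calpain inhibitor CAST among them. The cystatin gene CST3 belongs to neither part. The whole list had passed with the adipocyte score in the same 10 animals, but not with the connective tissue score (adjusted permutation p = 0.0691). Adjustment over 6 correlations does not cover this choice, so the p-values below only describe these animals. The cathepsins had r = 0.870 with the adipocyte score (permutation p = 0.00085, adjusted p = 0.0051, rho = 0.855, permutation p = 0.00309), with r = 0.840 without the 2 farthest animals. They had r = 0.828 with the connective tissue score (permutation p = 0.00299, adjusted p = 0.00774, rho = 0.867, permutation p = 0.00211; 0.765 without the 2 farthest) and r = 0.766 with the leukocyte score (permutation p = 0.00502, adjusted p = 0.00774, rho = 0.648, permutation p = 0.0489; 0.563 without the 2 farthest). The calpain system genes had r = 0.626 with the adipocyte score (permutation p = 0.0533, adjusted p = 0.064, rho = 0.394, permutation p = 0.264) with r = 0.364 without animal 5 and 0.215 without the 2 farthest. With the connective tissue score they had r = 0.437 (permutation p = 0.208, adjusted p = 0.208, rho = 0.333, permutation p = 0.349), which was 0.264 without animal 5 and 0.744 without the 2 farthest. With the leukocyte score they had r = 0.802 (permutation p = 0.00516, adjusted p = 0.00774, rho = 0.733, permutation p = 0.0206), which was 0.473 without the 2 farthest. The difference between both parts did not change with the adipocyte score past the threshold (r = 0.535, permutation p = 0.113).

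Transcripts of liver-made plasma proteins were highest in animals 3 and 7, and RNA of liver in these samples is a candidate explanation. Of 25 measured liver-secreted protein genes not looked at before, 19 (76%, exact 95% interval over genes 54.9% to 90.6%) had animals 3 and 7 as their highest pair, against 3.29% of all 9155 named genes; 6 of the 25 passed the level filter in muscle, and 3 of these 6 showed the pair. In animals 3 and 7 hemopexin (HPX) stood at 9.50 and 9.22 and albumin (ALB) at 12.78 and 13.02 on 1 of the 2 ALB probe sets that showed the pair, while 7 other probe sets annotated to ALB, the brightest among them, did not show it. The scaled hybridization control level as the cause is argued against by 4 arrays where it was higher than in both animals. It is read after the common scaling, so it cannot test array brightness itself. Whether liver RNA, if present, came from the animal or from handling was not tested. An acute phase response without liver RNA, as the whole cause, is weakly argued against by enzyme genes that are no acute phase proteins. Of 22 such genes, 8 (36.4%, interval 17.2% to 59.3%) showed the same pair, where that explanation needs under 10%. All intervals in this paragraph take genes as independent. Genes read on the same 2 arrays may move together, so the intervals can be too narrow. The share only just passed the one set beforehand for excluding it, and most of these enzymes were dim. Another count of 8 of the 22 lay above the filter level in at least 2 animals, and 5 of those showed the pair (62.5%, interval 24.5% to 91.5%). This second share cannot weigh on the question, because a gene that passes only through animals 3 and 7 must show the pair. BHMT was such a gene, at 7.55 and 7.50 in these animals and at most 5.81 in any other. CPS1 stood at 8.71 and 8.26 in animals 3 and 7 and at most 7.05 in any other. CYP27A1, bright in all animals, did not show the pair. Neither did CYP2E1, at 4.75 and 4.73 in animals 3 and 7, below its mean of 5.38. FBP1 (5.88 and 5.73, with 7.61 in animal 4) and ARG1 (6.19 and 6.30, with 7.38 in animal 5) were higher in another animal. The enzyme genes that did not show the pair leave liver RNA a candidate only.

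The leukocyte score had r = 0.842 with the adipocyte score (adjusted permutation p = 0.0691, n = 10), which did not pass over 55 pairs. A single array as the whole cause is argued against by r = 0.746 without animal 5. With the poly(A) covariate r was 0.764. That covariate stood apart in animal 5 alone (3.06, others 1.18 to 1.52), so it hardly tests labelling differences among the other arrays. Without the 2 animals farthest from the median adipocyte score r was 0.657 and rho 0.381. A lower share of muscle fibres, which raises all other cell types alike, stays open: the leukocyte minus endothelium score had r = 0.651 with the adipocyte score (permutation p = 0.0409, rho = 0.515, permutation p = 0.135), but r was 0.477 without animal 5 (exact permutation p = 0.195, n = 9) and 0.247 without the 2 farthest, and p was 0.05 or more with 8 of the 10 animals left out in turn. The endothelium score itself had r = 0.673 with the adipocyte score (adjusted permutation p = 0.161). A larger share of immune cells in samples with more fat cells may also account for it, a hypothesis found on these data and not tested by itself.

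Shuffling the score over the animals tested chance for the counts of genes, with 100 orders each, the real one included. For the adipocyte score 1 of the 100, the real order itself, gave as many as the real 15 genes. The highest other gave 14, so a count near the real one can arise by chance, which is not excluded. For the connective tissue score 1 of the 100 gave as many as 5, the highest other giving 2. For the fibre score the real count was 0, which every order must reach, so its 100 of 100 tests nothing. The highest other gave 1.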
